A study of Homo sapiens with 18 samples.

How the data were processed

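Messenger RNA was measured in THESC cells, an established, telomerase-immortalised line of human endometrial stromal cells that had been engineered with CRISPR guide RNAs. The labels describe 3 lines: one carrying a non-targeting guide (NT cells, labelled wild type), one carrying guides named U1U2 (U1U2 cells, labelled as having equivalent PGRA and PGRB), and one carrying a promoter guide (promoter cells, labelled PGRB-dominant). Each line was kept for 72 hours in vehicle (0.01% ethanol) or in 1 µM medroxyprogesterone acetate (MPA), a synthetic progestin, and each of the 6 groups holds 3 libraries, 18 in all. Per the labels' protocols, total RNA was column-purified with DNase digestion and libraries were made with a stranded poly(A) mRNA kit. The labels give all 18 libraries one batch, so no comparison could be repeated within batches. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

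The authors deposited a table of whole-number read counts per gene and a table of log2 CPM values. STAR 2.6.0c, the genome build hg38, R 4.4.1 and edgeR 4.2.2 are named, per the submitters' processing notes; which step each served, the read counter, its strand setting and the gene annotation were not given in the sources used here. The deposited counts covered 78724 genes, of which 40165 had at least 1 count, and every gene had an identifier. The deposited log2 CPM table held 10402 genes; all 187236 of its values lay within 5e-09 of the log2 CPM that edgeR gives from the deposited counts with TMM factors and a prior count of 2, so that table holds the same measurement and entered no test. Counts are summed per gene, so they cannot separate the PGRA and PGRB transcripts, which share most of their sequence. Because the counter's strand setting is unknown, reads of overlapping antisense genes cannot be told apart with certainty, and genes with near-identical copies, such as ribosomal protein pseudogenes, may have gained or lost shared reads.

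Total counts per library ran from 11.9 to 33.4 M (median 22.9 M). The 10 most abundant genes took 3.56% to 5.40% of the counts and mitochondrial genes 1.63% to 3.03%. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom between 1.95 and 35.1, so none was treated as a repeat deposit.

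The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at its minimum count of 10, which left 15558 genes. A quasi-likelihood model with 1 term per group was fitted to all 18 libraries with TMM factors, so that all groups share the estimate of spread (common biological coefficient of variation 0.129). It gave 12 contrasts: MPA against vehicle in each line, each pair of lines in vehicle, each pair of lines in MPA, and the 3 pairwise differences of MPA responses. P-values were adjusted over the 15558 genes with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05; an adjusted p printed for a gene is from this test. A log2 fold change is given with its standard error, and every comparison of 2 groups sets 3 libraries against 3. Correlations of fold changes are across genes, which are not independent replicates. Gene positions were taken from GENCODE 29, on the GRCh38 assembly, which matched 14700 of the tested genes (94.5%).

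The groups, contrasts, test, gene lists and naming rule were fixed before the data were examined. The named genes were, for the first 5 contrasts, the 12 with the largest positive and the 12 with the largest negative log2 fold change, and for the others the 8 and 8, among called genes with a mean log2 CPM of at least 1, a symbol that is not clone-based and, in comparisons of 2 groups, no overlap between the libraries of the groups, which chance gives to 10% of genes. Members of the gene lists and PGR could always be named, and the text names some of these genes, not all. A few of them are not reported here. The 20 lists, written from general knowledge with 551 genes of which 423 were measured, are decidual markers, steroid receptor-induced genes, steroid receptors and cofactors, the PGR neighbourhood on chromosome 11, fibrillar and basement matrix genes, matrix-degrading enzymes and inhibitors, cytokines and chemokines, interferon-stimulated genes, mitotic and replication genes, contractile and myofibroblast genes, angiogenic and vascular factors, WNT and BMP pathway genes, unfolded protein and amino acid stress genes, sterol synthesis genes, glycolytic and hypoxia genes, p53 target genes, and markers of epithelial, endothelial, leukocyte and stromal cells. The list of cytokines and chemokines also holds genes that encode neither, such as TNFAIP3, NFKBIA, PTGS2, ICAM1 and SOD2. Lists were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM, with an inter-gene correlation preset to 0.01 and again with an estimated correlation, adjusted over the 20 lists of a contrast. Where a group's summed count of a gene was 0, the fold is a lower bound against 3 counts over the group; such bounds and intervals cover counting error only.

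Counts were simulated for all 18 libraries from the NT vehicle means, so they held no line or MPA effect beyond the genes changed. In each simulation 100 genes were changed 1.5-fold and 100 changed 2-fold, leaving out genes with low NT vehicle means. There edgeR recovered 38% and 79% in the simulated MPA response of NT cells (10 false calls among 15259 genes). It recovered 44% and 74% in the simulated comparison of promoter with NT cells in vehicle (7 among 15273). In the simulated difference of responses it recovered 11% and 58% (3 among 15265). DESeq2 recovered 48% and 85%, 55% and 79%, and 30% and 70%, with 24, 21 and 18 false calls among 15558 genes. In a simulated list of sterol synthesis genes all changed by 1.5-fold, camera called that list with both kinds of correlation and 0 of the 19 other lists. Genes were drawn independently there, so the simulation could not test the preset correlation for lists whose members vary together. In the measured libraries the estimated correlation was 0.327 for mitotic and replication genes and 0.212 for matrix genes.

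Each result was recomputed with DESeq2 1.42.0, limma-voom, RLE size factors, library sizes alone, no filter, a filter of 50 counts in 3 libraries, a replicate block, only the groups compared, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and without each library in turn. Offsets for GC content and transcript length (a spline with 5 degrees of freedom, for the 94.5% of genes with annotation) and libraries thinned to 11932474 counts were added after the data were seen. Comparisons that share control libraries were set beside 20 simulations of unchanged groups. Genes were drawn independently there too, so these simulations lacked variation that many genes share within a library. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.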

Results

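The libraries profiled human endometrial stromal cells of the THESC line, the connective-tissue cells of the uterine lining, which differentiate into decidual cells under progesterone. Guide RNAs had been used to activate PGR, the gene of the progesterone receptor, in U1U2 cells and in promoter cells, with its isoforms A and B at different ratios, and NT cells with a non-targeting guide were the control. Each line was cultured with vehicle or with 1 µM MPA for 72 hours, in 3 libraries per group. Mean totals were 16.1 M counts in NT vehicle, 23.1 M in NT MPA, 27.9 M in U1U2 vehicle, 24.6 M in U1U2 MPA, 27.1 M in promoter vehicle and 25.1 M in promoter MPA. NT vehicle replicate 1 was the shallowest library, with 11.9 M counts, and had the highest mitochondrial share, 3.03%, and 1305 CPM from ribosomal protein pseudogenes, against 516 to 818 in the other libraries. Transcripts of other cell types were scarce: PECAM1 (endothelial) had 0 to 4 counts per library, CDH5 (endothelial) 0 to 2, EPCAM (epithelial) 3 to 34 and PTPRC (leukocyte) 33 to 143.

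PGR (ENSG00000082175, a protein-coding gene at 11:101029624-101130524 on GRCh38) was far more abundant in both activated lines. In vehicle its mean was 140 ± 17.6 CPM (SD, n = 3) in NT cells, 596 ± 72.5 in U1U2 cells and 434 ± 40.1 in promoter cells. The log2 fold change was 2.09 ± 0.13 in U1U2 cells (adjusted p = 7.21e-08) and 1.63 ± 0.12 in promoter cells (adjusted p = 1.57e-06). MPA lowered PGR in every line, to 84.5 ± 9.65 CPM in NT cells, 260 ± 32.7 in U1U2 cells and 282 ± 19.4 in promoter cells. The log2 changes were -0.73 ± 0.12, -1.20 ± 0.12 and -0.62 ± 0.12 (adjusted p = 0.000881, 1.67e-06 and 0.00142). In MPA the activated lines still exceeded NT cells, by 1.62 ± 0.13 and 1.74 ± 0.13. Between promoter and U1U2 cells the main test, adjusted over all genes, called no difference in vehicle (-0.46 ± 0.12, adjusted p = 0.107) or in MPA (0.12 ± 0.12). A missing call does not show that PGR was equal in these lines. In vehicle every promoter library (395 to 475 CPM) lay below every U1U2 library (531 to 674 CPM). The vehicle difference passed with DESeq2 (-0.46), with no filter (-0.46) and with GC and length offsets (-0.35). By the main test the fall of PGR under MPA did not differ between lines past the threshold (adjusted p = 0.441, 0.787 and 0.451). The differences were -0.47 ± 0.17 for U1U2 minus NT, 0.11 ± 0.17 for promoter minus NT and 0.58 ± 0.17 for promoter minus U1U2. With GC and length offsets the difference for U1U2 minus NT passed, at -0.49. These sums over the gene say nothing of the ratio of its isoforms.

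**Figure D1:**
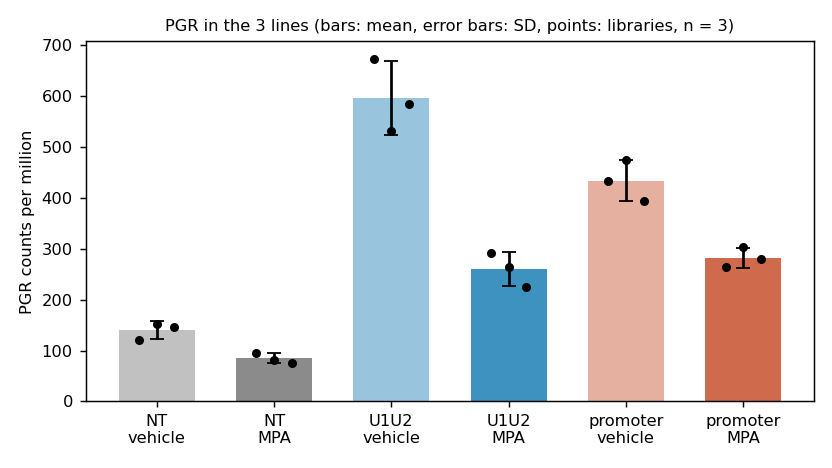
PGR in CPM (vertical axis) in the 6 groups of cell line and treatment (horizontal axis), with bars for the mean, error bars for the SD and points for the 3 libraries of each group. In vehicle the means were 140 in NT, 596 in U1U2 and 434 in promoter cells, and every library of the activated lines lay above every NT library.

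The MPA response of NT cells was measured at their own level of PGR. No group lacked PGR or had a receptor blocked, so which receptor carried the response was not tested. OMD, a leucine-rich proteoglycan of the matrix, rose by 3.89 ± 0.19. Higher too were FKBP5, a co-chaperone of steroid receptors (2.89 ± 0.10, from 16.1 to 120 CPM), PTGER2, a prostaglandin E2 receptor (2.83 ± 0.16), PAPLN (2.82 ± 0.23) and CORIN, the protease that activates atrial natriuretic peptide (2.65 ± 0.18). PER1, a circadian clock gene (2.26 ± 0.32), and ERRFI1, an inhibitor of the EGF receptor (2.14 ± 0.09), also rose. NPTX1, a neuronal pentraxin, fell from 124 to 11.1 CPM (-3.48 ± 0.11). SLC7A14 (-2.83 ± 0.17), MMP1, the interstitial collagenase (-2.54 ± 0.11), GRIN2A, a subunit of NMDA receptors (-2.28 ± 0.19), CCN3 (-2.19 ± 0.16) and TNFRSF11B, osteoprotegerin (-2.16 ± 0.13), fell as well. By edgeR's quasi-likelihood test 922 genes were called, 380 higher and 542 lower. Without NT vehicle replicate 2 the count was 612, with only the 2 groups fitted 491 and with GC and length offsets 1435.

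Of 20 measured steroid receptor-induced genes, 10 rose and 1 fell in NT cells (13 and 1 adjusted over the list alone), among them TSC22D3, the leucine zipper protein GILZ (1.74 ± 0.22), and CRISPLD2 (1.10 ± 0.10). The list moved up (camera adjusted p = 3.84e-12) and held at 0.00683 with an estimated correlation. Its median was 0.37 with ZBTB16 at the fold change edgeR gave and 0.37 without it. ZBTB16, a zinc finger transcription factor, had 0 counts over the 3 NT vehicle libraries and 528 over the 3 MPA libraries, at least 122-fold higher against a floor of 3 counts over the group. Sterol synthesis genes fell: 7 of 25 passed (9 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 3.08e-07, and 0.0208 with an estimated correlation). They included HMGCS1, an enzyme of the mevalonate pathway (-0.73 ± 0.12), MSMO1, a sterol oxidase (-0.64 ± 0.12), and INSIG1, the feedback regulator of sterol synthesis (-0.78 ± 0.10). Of 16 genes on the list of cytokines and chemokines, 1 rose and 4 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.00405, and 0.0313 with an estimated correlation). LIF (-1.69 ± 0.30) and the chemokine CXCL12 (-1.24 ± 0.07) fell. The gene that rose was no cytokine but TNFAIP3, an inhibitor of NF-kappa-B signalling (1.03 ± 0.11).

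Matrix genes changed in both directions in NT cells. Of 42 fibrillar and basement matrix genes, 11 rose and 3 fell (15 and 4 adjusted over the list alone). Fibronectin FN1 stood at 0.90 ± 0.19, nidogen NID1 at 0.84 ± 0.08 and fibrillin FBN2 at 0.86 ± 0.12, against the proteoglycans LUM at -0.98 ± 0.14 and DCN at -0.70 ± 0.12. The list passed with the preset correlation (camera adjusted p = 0.000243) and did not with the other (adjusted p = 0.353 with an estimated correlation). Of 25 decidual markers, 4 rose and 3 fell (6 and 6 adjusted over the list alone), and the list did not move as a whole (camera adjusted p = 0.664). Without NT vehicle replicate 3 or NT MPA replicate 2, 2 decidual markers rose. HSD11B1, the enzyme that makes cortisol from cortisone, rose (3.38 ± 0.30), and BMP2 (-1.77 ± 0.15) and IGFBP3 (-0.96 ± 0.09) fell. By camera in NT cells, interferon-stimulated genes were lower (median -0.17, adjusted p = 0.0203, lost at adjusted p = 0.421 with an estimated correlation). The PGR neighbourhood was lower (median -0.22, adjusted p = 0.00405, lost at adjusted p = 0.232 with an estimated correlation) and unfolded protein and amino acid stress genes were higher (median 0.20, adjusted p = 0.00405, lost at adjusted p = 0.387 with an estimated correlation). The neighbourhood list shares MMP genes with the list of matrix-degrading enzymes, among them MMP1, which fell in NT cells. A change of the locus as a whole therefore cannot be read from it. FOXO1, a transcription factor of decidualisation, was called at 0.45 ± 0.12 (adjusted p = 0.0286), but not without NT vehicle replicate 1, NT vehicle replicate 3, NT MPA replicate 1 or NT MPA replicate 2 (adjusted p up to 0.162), nor with only the 2 groups fitted. The classical decidual hormones PRL and IGFBP1 were near the limit of detection, at 0 to 7 counts per library in all 18 libraries. PRL had 1 count over the promoter vehicle libraries and 12 in MPA, a ratio of 13.0 in CPM with a 95% counting interval of 1.92 to 554, which leaves out the spread between libraries. The intervals of PRL in the other lines and of IGFBP1 in all lines included 1.

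In U1U2 cells MPA moved many of these genes too. OMD rose by 5.09 ± 0.21 and FKBP5 by 3.46 ± 0.10 (from 16.4 to 180 CPM). Also higher were APCDD1, a WNT inhibitor (3.81 ± 0.20), IMPA2, an inositol monophosphatase (3.35 ± 0.15, from 4.38 to 45 CPM), DEPP1, a FOXO target (3.31 ± 0.24), and NOG, the BMP antagonist noggin (3.23 ± 0.40). SLC7A14 (-3.79 ± 0.18), GRIN2A (-3.23 ± 0.20), NPTX1 (-3.02 ± 0.11), TNFRSF11B (-2.82 ± 0.14), the carboxypeptidase CPA4 (-2.73 ± 0.19) and MMP1 (-2.57 ± 0.11) fell. FOXO1 rose from 15.8 to 55.5 CPM (1.81 ± 0.12), HAND2, a transcription factor of the endometrial stroma, by 1.30 ± 0.20 and HSD11B1 by 4.79 ± 0.25. The edgeR test called 1814 genes, 846 higher and 968 lower. With only the 2 groups fitted the count was 1049.

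Of the steroid receptor-induced genes, 17 of 20 rose in U1U2 cells (18 adjusted over the list alone, camera adjusted p = 3.24e-22, and 0.000427 with an estimated correlation). The median was 0.89 with ZBTB16 at the fold change edgeR gave and 0.89 without it. KLF15 (2.19 ± 0.23) and CEBPD (1.40 ± 0.20), both transcription factors, were among the genes that rose. ZBTB16 went from 0 to 667 counts per group, at least 253-fold higher against the same floor. Sterol synthesis genes again moved down, with 11 of 25 called lower (14 adjusted over the list alone), a median of -0.41 and a camera adjusted p = 3.71e-08 (0.0132 with an estimated correlation). HMGCS1 stood at -0.93 ± 0.12 and the farnesyl diphosphate enzymes FDPS and FDFT1 at -0.58 ± 0.13 each. That count was 7 without U1U2 vehicle replicate 3 and 7 without U1U2 MPA replicate 2. Of 30 interferon-stimulated genes, 1 rose and 12 fell (1 and 13 adjusted over the list alone), such as MX1 (-1.63 ± 0.37) and IFIT1 (-1.12 ± 0.09). The camera test of that list passed with the preset correlation (adjusted p = 2.38e-06) and was lost in the other (adjusted p = 0.171 with an estimated correlation). Matrix genes had 17 higher and 5 lower of 42 (20 and 6 adjusted over the list alone; camera adjusted p = 9.54e-05), lost at adjusted p = 0.368 with an estimated correlation. Collagens COL1A1 (0.84 ± 0.17) and COL7A1 (1.40 ± 0.27) rose. Of 25 decidual markers, 10 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.018), and the list's adjusted p = 0.171 with an estimated correlation. Contractile genes were higher by camera (median 0.28, adjusted p = 0.00892, lost at adjusted p = 0.389 with an estimated correlation), as were unfolded protein and amino acid stress genes (median 0.18, adjusted p = 0.018, lost at adjusted p = 0.599 with an estimated correlation).

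Promoter cells had the most called genes under MPA of the 3 lines. OMD rose by 5.58 ± 0.21, APCDD1 by 4.48 ± 0.18, FKBP5 by 4.07 ± 0.10 (from 20.8 to 348 CPM), IMPA2 by 3.72 ± 0.15, DEPP1 by 3.57 ± 0.25 and CPM, a membrane carboxypeptidase, by 3.23 ± 0.08 (from 26.7 to 250 in units of CPM). FOXO1 went from 17.4 to 116 CPM (2.73 ± 0.12), HAND2 rose by 1.83 ± 0.20 and HSD11B1 by 5.04 ± 0.23. SLC7A14 (-3.68 ± 0.19), MMP1 (-3.44 ± 0.11), CPA4 (-3.28 ± 0.20), NPTX1 (-3.25 ± 0.11) and the growth factors FGF9 (-2.77 ± 0.16) and BMP2 (-2.71 ± 0.16) fell. The edgeR test called 2339 genes, 1032 higher and 1307 lower.

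**Figure D2:**
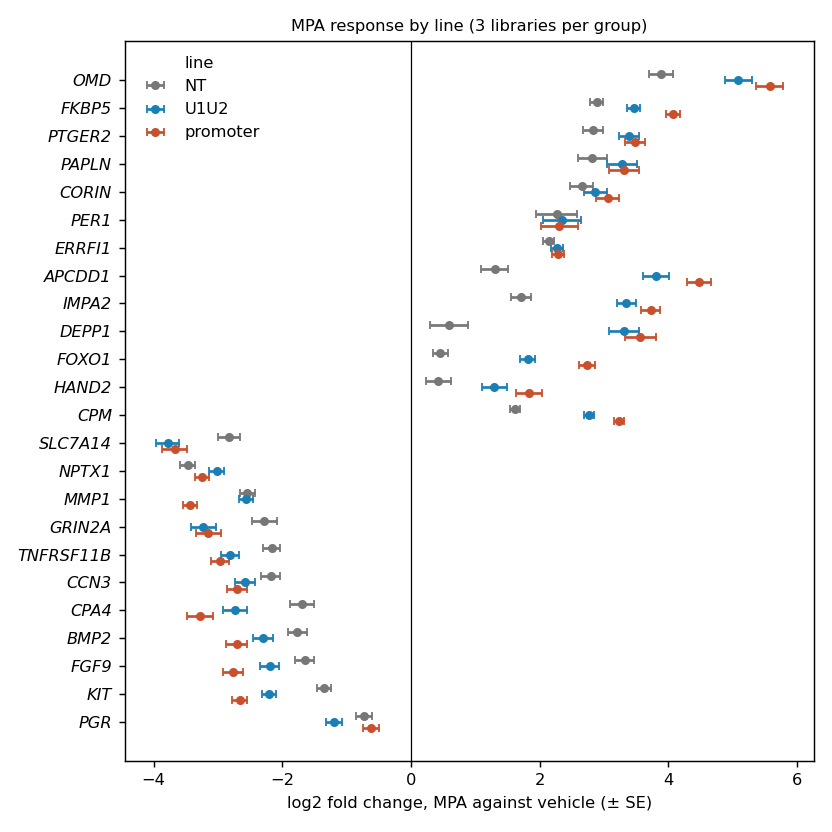
Log2 fold change of 24 genes in MPA against vehicle (horizontal axis, with the standard error) for NT, U1U2 and promoter cells (colours), each from 3 libraries per group. OMD stood at 3.89, 5.09 and 5.58 and FKBP5 at 2.89, 3.46 and 4.07, while NPTX1 stood at -3.48, -3.02 and -3.25.

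Steroid receptor-induced genes rose in promoter cells in 16 of 20 cases (16 adjusted over the list alone; camera adjusted p = 3.07e-19, and 0.000857 with an estimated correlation), with a median of 1.01 with or without ZBTB16. That gene had 1 count over the promoter vehicle libraries and 1552 in MPA, a ratio of 1675 in CPM with a 95% counting interval of 300 to 66216. Against the floor of 3 counts used for the other lines the ratio was 558. Sterol synthesis genes fell in 14 of 25 cases (19 adjusted over the list alone; median -0.62; camera adjusted p = 1.07e-10, and 0.00467 with an estimated correlation). They included HMGCS1 (-1.14 ± 0.13), FDFT1 (-0.68 ± 0.13) and INSIG1 (-1.18 ± 0.10). Of 16 genes on the list of cytokines and chemokines, 2 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.00189, and 0.0223 with an estimated correlation). IL33 stood at -2.56 ± 0.35, LIF at -1.42 ± 0.25, CXCL12 at -1.48 ± 0.07 and TNFAIP3 at 1.53 ± 0.11. In this line 25 of 40 mitotic and replication genes fell (30 adjusted over the list alone; median -0.52). Among them were cyclin CCNB1 (-0.91 ± 0.22), the kinase CDK1 (-0.69 ± 0.11), topoisomerase TOP2A (-0.57 ± 0.13) and CDC6, a loader of the replication helicase (-0.71 ± 0.11). The camera test of that list passed with the preset correlation (adjusted p = 9.59e-15) and was lost at adjusted p = 0.125 with an estimated correlation.

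**Figure D3:**
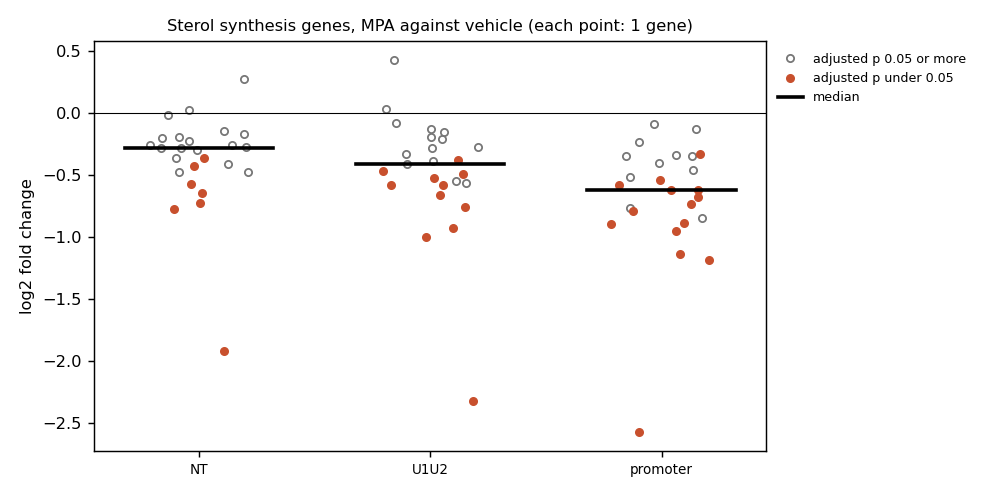
Log2 fold change in MPA against vehicle (vertical axis) of the 25 measured sterol synthesis genes in NT, U1U2 and promoter cells (horizontal axis); each point is 1 gene, filled at an adjusted p under 0.05, and the bar is the median. The medians were -0.29, -0.41 and -0.62, and 7, 11 and 14 genes fell.

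Matrix genes in promoter cells comprised 19 that rose and 5 that fell of 42 (19 and 7 adjusted over the list alone; camera adjusted p = 3.24e-05), lost at adjusted p = 0.269 with an estimated correlation. The number that fell was 2 without promoter vehicle replicate 1, promoter MPA replicate 2 or promoter MPA replicate 3. The laminin chains LAMA2 (1.74 ± 0.10) and LAMB1 (0.93 ± 0.10) rose and LAMA4 (-0.75 ± 0.08) fell. Of the interferon-stimulated genes 3 rose and 8 fell of 30 (3 and 10 adjusted over the list alone; camera adjusted p = 0.00189, lost at adjusted p = 0.269 with an estimated correlation). Of these, 1 rose without promoter MPA replicate 1. IFIT1 stood at -1.33 ± 0.09. Of 25 decidual markers 8 rose and 6 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.0474, lost at adjusted p = 0.269 with an estimated correlation), with S100A4, a calcium-binding protein, at -1.76 ± 0.24. Matrix-degrading enzymes and inhibitors went both ways, 5 higher and 8 lower of 24 (8 and 11 adjusted over the list alone; camera adjusted p = 0.349). The protease ADAMTS2 rose by 2.41 ± 0.12 and the plasminogen activator PLAT by 1.33 ± 0.12, and the stromelysin MMP3 (-3.07 ± 0.31) and urokinase PLAU (-1.32 ± 0.18) fell. Angiogenic and vascular factors had 8 higher and 7 lower of 26 (10 and 9 adjusted over the list alone; camera adjusted p = 0.79), with NRP2 at 1.37 ± 0.08 and STC1 at -1.50 ± 0.18. WNT and BMP pathway genes had 7 higher and 7 lower of 31 (7 and 7 adjusted over the list alone; camera adjusted p = 0.687). They included ID1, a BMP target, at 1.74 ± 0.27, NOG at 2.96 ± 0.39 and the WNT antagonist SFRP1 at -1.87 ± 0.21.

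The remaining lists moved little as groups under MPA in promoter cells. Contractile and myofibroblast genes had a median of 0.16 (camera adjusted p = 0.0197, lost at adjusted p = 0.425 with an estimated correlation). ANKRD1, a stretch-responsive gene, rose by 2.61 ± 0.15 and smooth muscle actin ACTG2 by 1.46 ± 0.19. Unfolded protein and amino acid stress genes had a median of 0.17 (camera adjusted p = 0.0159, lost at adjusted p = 0.448 with an estimated correlation). The p53 target genes had a median of -0.23 (camera adjusted p = 0.0316, lost at adjusted p = 0.269 with an estimated correlation). Glycolytic and hypoxia genes (median -0.15, camera adjusted p = 0.226), steroid receptors and cofactors (0.02, 0.687) and the PGR neighbourhood on 11q22 (0.15, 0.74) did not pass. Of 28 glycolytic and hypoxia genes 3 rose and 5 fell (3 and 6 adjusted over the list alone), or 2 and 2 without promoter vehicle replicate 1, 3 and 2 without promoter MPA replicate 2 and 2 and 3 without promoter MPA replicate 3. LDHA, a lactate dehydrogenase, rose (0.53 ± 0.12) and the enolase ENO2 fell (-1.07 ± 0.13). None of the cell-type lists passed camera. The adjusted p was 0.441 for 7 epithelial markers, 0.154 for 3 endothelial markers, 0.153 for 2 leukocyte markers and 0.687 for 18 stromal markers. Of the endothelial markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), the rise not being called without promoter vehicle replicate 2, promoter vehicle replicate 3 or promoter MPA replicate 3, and TEK stood at -0.78 ± 0.07. Of the stromal markers 3 rose and 6 fell (4 and 6 adjusted over the list alone), or 2 and 3 without promoter MPA replicate 3. Of the leukocyte markers PTPRC fell (-1.12 ± 0.17).

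The 3 lines shared much of their response to MPA, and these 3 comparisons share no libraries. Of the called genes, 274 rose and 348 fell in all lines, where independent lists would share 1.37 and 2.83. U1U2 and promoter cells shared 633 genes that rose and 727 that fell (56.1 and 81.3 for independent lists), with a Pearson correlation of fold changes across genes of 0.801 and a Spearman correlation of 0.647. NT and U1U2 cells shared 292 and 395 (20.7 and 33.7 for independent lists; Pearson 0.606, Spearman 0.349), and NT and promoter cells 300 and 385 (25.2 and 45.5; Pearson 0.534, Spearman 0.250), with 1 gene called in opposite directions.

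Before any progestin, few genes beyond PGR were steadily called between U1U2 and NT cells. By the edgeR test 2526 of 15558 genes had an unadjusted p under 0.05. The low count of calls therefore does not mean that few genes differed. PAPPA2, a protease that cleaves insulin-like growth factor binding proteins (1.60 ± 0.22), the laminin chain LAMA1 (0.87 ± 0.09) and SEL1L3 (0.68 ± 0.09) were higher. IGF2, insulin-like growth factor 2 (-1.82 ± 0.27, from 48.1 to 13.6 CPM), the adhesion receptor ADGRF4 (-1.80 ± 0.19), synaptotagmin SYT1 (-1.19 ± 0.17) and the plasminogen activator PLAT (-0.75 ± 0.12) were lower. These 7 genes and PGR were called without each library in turn, whereas 16 of the other named genes were not. With only the 2 groups fitted, PAPPA2, SEL1L3, IGF2, SYT1 and PLAT were not called. The edgeR test called 178 genes, 67 higher and 111 lower (37.6% higher, and 56.3% with library sizes alone in place of TMM factors). This count rests on single libraries. It was 23 without NT vehicle replicate 2, 28 without U1U2 vehicle replicate 2, 27 without U1U2 vehicle replicate 3 and 639 without U1U2 vehicle replicate 1. It was 4 with only the 2 groups fitted, 451 with DESeq2 and 808 with no filter. Camera placed decidual markers lower (median -0.25, and -0.27 without CNR1, which had too few counts in vehicle for a fold; adjusted p = 0.000438, lost at adjusted p = 0.0646 with an estimated correlation). Stromal markers were lower too (median -0.13, adjusted p = 0.00868, lost at adjusted p = 0.0646 with an estimated correlation). Angiogenic factors were lower (median -0.19, adjusted p = 0.00099, lost at adjusted p = 0.158 with an estimated correlation), as were steroid receptor-induced genes (median -0.09, and -0.11 without ZBTB16; adjusted p = 0.00868, lost at adjusted p = 0.219 with an estimated correlation). It placed mitotic and replication genes higher (median 0.23, adjusted p = 2.03e-06, lost at adjusted p = 0.331 with an estimated correlation).

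In vehicle, promoter cells differed from NT cells in many cell-cycle genes. The named genes that were higher included PIMREG, a mitotic regulator (1.34 ± 0.20), CDCA5, the cohesion factor sororin (1.18 ± 0.20), KIF18B, a mitotic kinesin (1.15 ± 0.18), PLEKHG4 (1.56 ± 0.27), SYT7 (1.29 ± 0.24) and GRPR, the receptor of gastrin-releasing peptide (1.17 ± 0.16). IGF2 (-2.05 ± 0.27, from 48.1 to 11.5 CPM), IGSF10 (-1.78 ± 0.19), SPRY1, an inhibitor of receptor tyrosine kinase signalling (-1.69 ± 0.16), the parathyroid hormone receptor PTH1R (-1.67 ± 0.30), OMD (-1.53 ± 0.27) and the transcription factor SIX2 (-1.45 ± 0.19) were lower. Of the 40 mitotic and replication genes, 30 were higher (39 adjusted over the list alone), with a median of 0.67. CDC6 stood at 1.00 ± 0.11, TOP2A at 0.76 ± 0.13, the kinase AURKA at 0.74 ± 0.15, CDK1 at 0.69 ± 0.11 and cyclin CCNA2 at 0.65 ± 0.09. The camera test of that list passed with the preset correlation (adjusted p = 4.37e-30) and just missed in the other (adjusted p = 0.0587 with an estimated correlation). The mitochondrial share of counts parted the same libraries, at 2.51% to 3.03% in NT and 1.63% to 2.15% in promoter vehicle. The list's count was 17 without NT vehicle replicate 2 and 18 without promoter vehicle replicate 1.

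Other lists passed camera in that comparison with the preset correlation alone. Glycolytic and hypoxia genes were higher (median 0.22, adjusted p = 0.0086, lost at adjusted p = 0.363 with an estimated correlation). Decidual markers were lower (median -0.21, and -0.22 without CNR1; adjusted p = 0.0171, lost at adjusted p = 0.152 with an estimated correlation), as were WNT and BMP pathway genes (median -0.20, and -0.20 without NKD1; adjusted p = 0.0484, lost at adjusted p = 0.134 with an estimated correlation). Of 3 endothelial markers 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.178), the lower one being called only with all libraries or without NT vehicle replicate 3. Of 42 matrix genes 7 were lower (7 adjusted over the list alone; camera adjusted p = 0.0691), such as DCN (-0.82 ± 0.12), LUM (-0.66 ± 0.14) and LAMA2 (-0.74 ± 0.10). Angiogenic factors were lower by camera (adjusted p = 0.00277, lost at adjusted p = 0.152 with an estimated correlation), with PDGFD at -0.97 ± 0.13 and ANGPT1 at -0.73 ± 0.12. Stromal markers were lower by camera (median -0.10, adjusted p = 0.0442, lost at adjusted p = 0.134 with an estimated correlation). MMP1 (0.78 ± 0.10) and PLAU (1.04 ± 0.18) were higher. Beside PGR, TRPC6, a calcium channel gene further along chromosome 11 (start 101451564), was lower (-0.90 ± 0.11), as was PGR-AS1 (-1.66 ± 0.27), an antisense transcript that overlaps the PGR start and whose reads cannot be told from those of PGR with certainty. Of 86 tested ribosomal protein pseudogenes 29 were lower in promoter than in NT cells in vehicle, and 14 without NT vehicle replicate 1. The edgeR test called 1050 genes, 478 higher and 572 lower (45.5% higher, and 56.9% with library sizes alone), 522 without NT vehicle replicate 2, 472 without promoter vehicle replicate 1 and 435 with only the 2 groups fitted.

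**Figure D4:**
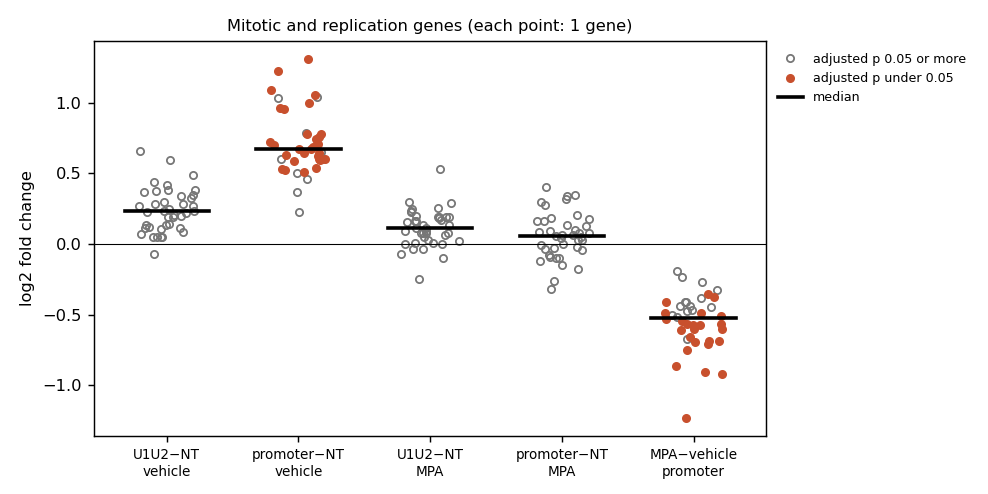
Log2 fold change (vertical axis) of the 40 measured mitotic and replication genes in 5 comparisons (horizontal axis): U1U2 and promoter cells against NT cells in vehicle and in MPA, and MPA against vehicle in promoter cells. Each point is 1 gene, filled at an adjusted p under 0.05, and the bar is the median; the medians were 0.23, 0.67, 0.11, 0.06 and -0.52.

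Few genes were called between promoter and U1U2 cells in vehicle, though 1349 of 15558 had an unadjusted p under 0.05 by the edgeR test. HLA-DMA, which loads peptides on class II molecules (1.05 ± 0.15), MARCHF3, a ubiquitin ligase (1.06 ± 0.16), SLC7A2, an arginine transporter (0.98 ± 0.11), and the lysophosphatidic acid receptor LPAR3 (0.90 ± 0.14) were higher in promoter cells. IGSF10 (-1.16 ± 0.18), the cadherin FAT3 (-0.90 ± 0.14) and TRPC6 (-0.89 ± 0.11) were lower. By camera, matrix genes were lower (median -0.05, adjusted p = 0.0256, lost at adjusted p = 0.642 with an estimated correlation). Cytokines and chemokines were higher (median 0.15, adjusted p = 0.0256, lost at adjusted p = 0.0981 with an estimated correlation), as were glycolytic and hypoxia genes (median 0.14, adjusted p = 0.0285, lost at adjusted p = 0.642 with an estimated correlation) and endothelial markers (median 0.22, adjusted p = 0.0285, lost at adjusted p = 0.59 with an estimated correlation). With only the 2 groups fitted, HLA-DMA, MARCHF3, LPAR3, FAT3 and CDC6 were not called. Mitotic and replication genes were higher in promoter cells here too, with 10 of 40 called (31 adjusted over the list alone), a median of 0.46 and a camera adjusted p = 4.69e-34 (0.0379 with an estimated correlation). CDC6 stood at 0.66 ± 0.11. The count of 10 was 5 without U1U2 vehicle replicate 1, 3 without U1U2 vehicle replicate 2, 2 without U1U2 vehicle replicate 3, 3 without promoter vehicle replicate 1, 3 without promoter vehicle replicate 2 and 5 without promoter vehicle replicate 3. The edgeR test called 122 genes, 82 higher and 40 lower, and with those same libraries left out in that order 64, 39, 44, 54, 52 and 43.

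The lines activated for PGR had 128 called changes in common in vehicle, 32 higher and 96 lower, against 2.06 and 4.08 for independent lists. With library sizes alone in place of TMM factors they were 65 and 74. The Pearson correlation of their fold changes across genes was 0.765, against a mean of 0.574 in 20 simulations of unchanged groups, and the covariance was 0.120 against 0.0403, a difference of 0.0795. Both comparisons use the 3 NT vehicle libraries, which are too few to divide, so part of the excess may come from the shared controls. For the same reason these lists of calls are not independent. The simulations drew genes independently and so lacked variation that many genes share within a library. Such variation in the shared controls could lift the observed values above the simulated ones.

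In MPA, U1U2 cells had more DEPP1 (2.92 ± 0.23, from 1.59 to 12.2 CPM), IMPA2 (1.83 ± 0.13), G0S2, an inhibitor of triglyceride breakdown (1.62 ± 0.17), PAPPA2 (1.59 ± 0.19), TGFB2 (1.53 ± 0.17), HSD11B1 (1.40 ± 0.19) and FKBP5 (0.59 ± 0.09). They had less ADGRF4 (-1.86 ± 0.20), IGSF10 (-1.84 ± 0.19), RIPOR2 (-1.81 ± 0.21) and the iron exporter SLC40A1 (-1.17 ± 0.18). In promoter cells APCDD1 (2.87 ± 0.16), DEPP1 (2.67 ± 0.23), IMPA2 (2.20 ± 0.14), G0S2 (2.20 ± 0.17), CAMK1G (2.18 ± 0.23), RGCC, a regulator of the cell cycle (2.00 ± 0.09), FOXO1 (1.75 ± 0.12) and FKBP5 (1.54 ± 0.09) were higher. IGSF10 (-2.45 ± 0.20), C11orf87 (-2.05 ± 0.15), SLC40A1 (-1.64 ± 0.19) and FGF9 (-1.60 ± 0.16) were lower. Promoter cells exceeded U1U2 cells in APCDD1 (1.52 ± 0.15), FOXO1 (1.06 ± 0.11), FKBP5 (0.95 ± 0.09) and RGCC (0.74 ± 0.09), with GPRC5A (-1.05 ± 0.12), the phosphodiesterase PDE1A (-0.84 ± 0.11) and KIT, the receptor of stem cell factor (-0.82 ± 0.11), lower.

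Steroid receptor-induced genes in MPA were higher by camera in U1U2 than in NT cells (median 0.21, adjusted p = 6.13e-05, lost at adjusted p = 0.101 with an estimated correlation). They were also higher in promoter than in NT cells (median 0.30, adjusted p = 1.91e-06, lost at adjusted p = 0.0752 with an estimated correlation). Stromal markers were lower in U1U2 than in NT cells (median -0.16, adjusted p = 0.0191, lost at adjusted p = 0.101 with an estimated correlation), and so were interferon-stimulated genes (median -0.22, adjusted p = 0.00731, lost at adjusted p = 0.497 with an estimated correlation). In promoter against U1U2 cells, steroid receptor-induced genes were higher (median 0.09, adjusted p = 0.00517, lost at adjusted p = 0.29 with an estimated correlation) and the PGR neighbourhood was lower (median -0.14, adjusted p = 0.00126, lost at adjusted p = 0.287 with an estimated correlation). The WNT and BMP pathway genes were lower in promoter than in U1U2 cells (median -0.12, adjusted p = 0.00126, and 0.0166 with an estimated correlation). The edgeR test called 268 genes for U1U2 against NT, 122 higher and 146 lower (164 without NT MPA replicate 1, 173 without NT MPA replicate 2, 154 without U1U2 MPA replicate 2). It called 645 for promoter against NT, 276 higher and 369 lower (394 without promoter MPA replicate 2, 390 without promoter MPA replicate 3). For promoter against U1U2 it called 51, 30 higher and 21 lower (16 without U1U2 MPA replicate 1, 30 without U1U2 MPA replicate 2, 25, 15 and 17 without promoter MPA replicates 1, 2 and 3). The changes from NT shared 99 higher and 133 lower genes (2.16 and 3.46 for independent lists), with a covariance 0.0572 above the simulated one; part of this excess may come from the shared NT MPA libraries.

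The difference of MPA responses asks whether the lines answered the progestin differently. The labels describe 1 line for each kind of guide. An effect of activating PGR therefore cannot be told apart from other differences between the lines, here or in the comparisons of lines above. In U1U2 cells the rise under MPA exceeded that of NT cells for DEPP1 (by 2.72 ± 0.38), APCDD1 (2.51 ± 0.30), G0S2 (1.91 ± 0.25), IMPA2 (1.64 ± 0.21), RGCC (1.54 ± 0.13) and FOXO1 (1.36 ± 0.17). FRY had a lower response (-0.82 ± 0.13), but not with only the groups compared fitted, and G0S2 was not called with libraries thinned to one total. In promoter cells it exceeded that of NT cells for APCDD1 (3.17 ± 0.29), DEPP1 (2.97 ± 0.39), FOXO1 (2.28 ± 0.17), the amino acid transporter SLC7A8 (2.27 ± 0.29), SPRY1 (2.04 ± 0.21), IMPA2 (2.02 ± 0.21), HAND2 (1.41 ± 0.28), FKBP5 (1.18 ± 0.14) and LAMA2 (1.08 ± 0.13). Responses were lower in promoter cells for CPA4 (-1.59 ± 0.27), PIMREG (-1.54 ± 0.29), the serotonin receptor HTR2B (-1.34 ± 0.17), KIT (-1.32 ± 0.16), MMP1 (-0.89 ± 0.15) and the replication genes MCM4 (-0.61 ± 0.11) and RRM2 (-0.63 ± 0.12). Already in vehicle, SPRY1 and LAMA2 were lower and PIMREG and MMP1 higher in promoter than in NT cells. Most of the difference in response of each of these genes therefore lay in vehicle, not in MPA. For steroid receptor-induced genes, none differed between U1U2 and NT by edgeR over all genes (12 at an unadjusted p under 0.05, 10 adjusted over the list alone, 1 by DESeq2, 0 by limma-voom), and 1 differed without U1U2 vehicle replicate 1. Of the 20, 3 differed between promoter and NT (8 adjusted over the list alone). As lists they moved up in both (camera adjusted p = 8.24e-08 and 8.13e-09, and 0.0386 and 0.0281 with an estimated correlation).

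Mitotic and replication genes had a lower MPA response in promoter than in NT cells, with a median difference of -0.62 and 9 of 40 called (30 adjusted over the list alone; camera adjusted p = 3.24e-20, lost at adjusted p = 0.103 with an estimated correlation). The 9 became 2 without NT vehicle replicate 2, 4 without NT vehicle replicate 3, 3 without NT MPA replicate 3, 2 without promoter vehicle replicate 1, 5 without promoter vehicle replicate 2, 2 without promoter MPA replicate 1 and 3 without promoter MPA replicate 2. In MPA the median of these genes against NT cells was 0.06 in promoter cells (camera adjusted p = 0.361) and 0.11 in U1U2 cells (camera adjusted p = 0.0191, lost at adjusted p = 0.868 with an estimated correlation). In vehicle the median was 0.67 in promoter cells, so most of their difference in response lay in vehicle, not in MPA.

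For U1U2 minus NT the edgeR test called 34 genes, 23 with a higher and 11 with a lower response (67.6% higher, and 52.9% with library sizes alone). It called 8 without NT vehicle replicate 2, 15 without NT vehicle replicate 3, 20, 14 and 19 without NT MPA replicates 1, 2 and 3, 11 and 12 without U1U2 vehicle replicates 2 and 3, and 11 and 20 without U1U2 MPA replicates 2 and 3. DESeq2 called 115. For promoter minus NT it called 242, 125 higher and 117 lower (116 without NT vehicle replicate 2, 145 without NT vehicle replicate 3, 156 without NT MPA replicate 3, 119 without promoter vehicle replicate 1, and 132, 137 and 135 without promoter MPA replicates 1, 2 and 3). The differences from NT shared 20 genes with a higher and 9 with a lower response (0.185 and 0.0827 for independent lists), or 16 and 14 with library sizes alone. Their covariance was 0.0865 above the simulated one, part of which may come from the shared NT libraries. Promoter minus U1U2 gave 2 genes, LAMA2 (0.96 ± 0.13), a laminin chain, and DTL (-0.87 ± 0.11), which marks replication factors for degradation. Neither was called without U1U2 MPA replicate 2 or promoter MPA replicate 1 (adjusted p = 0.0510), with a replicate block or with only the groups compared fitted. DESeq2 called 57 genes and limma-voom 3, and 804 genes had an unadjusted p under 0.05. DTL went from 38.9 to 21.2 CPM in promoter cells and from 23.4 to 23.3 in U1U2 cells, so most of its difference lay in vehicle.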

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

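The tests of the size of the MPA response, of the ribosomal pseudogenes without 1 NT vehicle library and of the structure behind the exchanged samples were chosen only after the result was seen. Genes and lists were singled out where the MPA response differed between 2 lines by a test of the difference itself, and 3 further patterns were chosen for weighing. In U1U2 minus NT, 34 genes differed. DEPP1 had a log2 difference of 2.72, APCDD1 2.51, G0S2 1.91, IMPA2 1.64, RGCC 1.54, FOXO1 1.36 and FRY -0.82, and each was called with any 1 library left out. Of the 16 named genes of this difference, 5 were called in every other setting; FRY was not called with only the groups compared fitted, and G0S2 was not called with thinned libraries.

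Other named genes of U1U2 minus NT lost the call without single libraries. ABCA8 (1.72) lost it without NT vehicle replicates 2 and 3, NT MPA replicates 1, 2 and 3, U1U2 vehicle replicates 1, 2 and 3, and U1U2 MPA replicates 1 and 2, each left out alone (adjusted p up to 0.159). MAP2 (1.49) lost it without NT vehicle replicates 2 and 3, NT MPA replicate 2, U1U2 vehicle replicates 2 and 3, and U1U2 MPA replicate 2 (up to 0.0834). HCP5 (-1.14) lost it without replicates 2 and 3 of each of the 4 groups (up to 0.0834). HTR2B (-0.98) lost it without replicates 2 and 3 of NT vehicle, U1U2 vehicle and U1U2 MPA (up to 0.0803). SYTL4 (-0.89) lost it without NT vehicle replicate 2 and U1U2 vehicle replicate 2 (up to 0.0763). KIT (-0.86) lost it without NT vehicle replicate 2 and replicates 2 and 3 of NT MPA, U1U2 vehicle and U1U2 MPA (up to 0.103). MEST (-0.77) lost it without each of the 6 NT libraries and without replicates 2 and 3 of U1U2 vehicle and U1U2 MPA (up to 0.132). C1orf115 (-0.69) lost it without every library but U1U2 vehicle replicate 1 (up to 0.161). SYPL2 (-0.62) lost it without replicates 2 and 3 of NT vehicle, NT MPA and U1U2 vehicle and without U1U2 MPA replicates 1, 2 and 3 (up to 0.153).

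In promoter minus NT, 242 genes differed. APCDD1 stood at 3.17, DEPP1 at 2.97, FOXO1 at 2.28, CAMK1G at 2.27, SLC7A8 at 2.27, SPRY1 at 2.04, IMPA2 at 2.02 and G0S2 at 2.00. Lower responses were seen for CPA4 (-1.59), PIMREG (-1.54), HCP5 (-1.38), HTR2B (-1.34) and KIT (-1.32). For SPRY1, lower in promoter than in NT cells in vehicle, and PIMREG, higher there, most of the difference lay in vehicle. MTFR2 (-1.37) lost the call without NT vehicle replicate 2, promoter vehicle replicate 1, and promoter MPA replicates 1 and 3 (adjusted p up to 0.0821). UCP2 (-1.30) lost it without NT vehicle replicates 2 and 3, NT MPA replicates 2 and 3, promoter vehicle replicate 1, and promoter MPA replicates 1, 2 and 3 (up to 0.138). RMI2 (-1.28) lost it without NT vehicle replicate 2, promoter vehicle replicates 1 and 2, and promoter MPA replicates 1 and 3 (up to 0.0879). In promoter minus U1U2, 2 genes differed, LAMA2 (0.96) and DTL (-0.87), and both lost the call without U1U2 MPA replicate 2 or promoter MPA replicate 1 (adjusted p = 0.0510). For DTL, higher in promoter than in U1U2 cells in vehicle, most of the difference lay in vehicle.

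As lists, in U1U2 minus NT the median difference was 0.29 for decidual markers (0.20 without CNR1, which had too few counts in vehicle for a fold; camera adjusted p = 0.00635, adjusted p = 0.143 with an estimated correlation), 0.32 for steroid receptor-induced genes (0.34 without ZBTB16) and -0.32 for interferon-stimulated genes (camera adjusted p = 0.000508, adjusted p = 0.295 with an estimated correlation). It was 0.20 for angiogenic and vascular factors (camera adjusted p = 0.00635, adjusted p = 0.295 with an estimated correlation) and 0.20 for WNT and BMP pathway genes (0.22 without NKD1; camera adjusted p = 0.0434, adjusted p = 0.132 with an estimated correlation). In promoter minus NT it was 0.12 for decidual markers (0.08 without CNR1; camera adjusted p = 0.0392, adjusted p = 0.289 with an estimated correlation), 0.47 for steroid receptor-induced genes (0.52 without ZBTB16) and -0.62 for mitotic and replication genes (adjusted p = 0.103 with an estimated correlation). It was 0.23 for angiogenic and vascular factors (camera adjusted p = 0.0198, adjusted p = 0.358 with an estimated correlation) and -0.35 for sterol synthesis genes (camera adjusted p = 0.0113, adjusted p = 0.289 with an estimated correlation). In promoter minus U1U2 it was -0.26 for cytokines and chemokines (camera adjusted p = 0.00264, and 0.0352 with an estimated correlation), -0.53 for mitotic and replication genes (camera adjusted p = 1.55e-28, and 0.0352 with an estimated correlation) and -0.21 for sterol synthesis genes (camera adjusted p = 0.0375, adjusted p = 0.372 with an estimated correlation). With 1 library left out, the mitotic median for promoter against U1U2 cells was 0.39 to 0.50 in vehicle and -0.11 to 0.02 in MPA. Against NT cells it was 0.61 to 0.71 in vehicle and 8.67e-05 to 0.12 in MPA. Most of both mitotic differences therefore lay in vehicle, not in MPA.

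Samples were exchanged between lines within each treatment to see how often other groupings gave as many genes. For U1U2 minus NT, 6 of 100 splits gave at least 34 genes, the real one included, and the highest other gave 2420. For promoter minus NT, 5 of 100 gave at least 242, with 1345 as the highest other, and for promoter minus U1U2, 6 of 100 gave at least 2, with 125 as the highest other. Of the other splits with as many genes, 5 of 5, 4 of 4 and 4 of 5 exchanged 2 or 3 vehicle libraries per line, which brings the line effects into the difference, so they do not show chance alone, and chance was not excluded for these 3 counts. Splits with many more genes than the real one point to a structure of the samples: exchanging the line labels of all vehicle libraries turns the difference of responses into the sum of the line effects, and gave 493, 1345 and 125 genes. The split with 2420 genes exchanged 1 MPA and 2 vehicle libraries of each line and ranked 1 of 100 in its separation along the second axis of variation within groups.

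For the 9 comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. In each, 1 split of the 10, the real one, gave as many genes: 922, 1814 and 2339 for MPA in NT, U1U2 and promoter cells, 178, 1050 and 122 for the lines in vehicle and 268, 645 and 51 for the lines in MPA. The highest other was 32 for U1U2 against NT in vehicle and 0 for the other 8.

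Promoter cells had 2.54 times as many called MPA-responsive genes as NT cells, and with only the groups compared fitted the counts were 2839 and 491. Counts of called genes also depend on the spread between replicates, which was not weighed here. Depth and a single library were argued against as the whole cause: the ratio was 2.38 with libraries thinned to one total, and at its lowest 1.79, without promoter vehicle replicate 1 (3.63 without NT vehicle replicate 2). The mean response of the genes called in the line not compared gave a score with n = 3 per group, compared by a two-sided exact permutation within treatments (400 permutations, smallest p = 0.005): 1.38 in U1U2 against 0.86 in NT cells (exact permutation p = 0.01), 1.77 in promoter against 1.06 in NT cells (p = 0.08) and 1.96 in promoter against 1.84 in U1U2 cells (p = 0.325). Vehicle labels are exchanged too, so p depends on the vehicle difference, which was 0.0317 for promoter against NT, beside 0.736 in MPA (SDs of 0.0128 to 0.0785), and this pair could hardly reach a small p, so its p decides nothing. The vehicle difference was -0.128 for U1U2 against NT, beside 0.388 in MPA (SDs of 0.0574 to 0.0986), so part of the difference that passed lay in vehicle. Both comparisons with NT cells also used genes called in the other activated line. Fold changes of U1U2 and promoter cells correlated at Pearson 0.801, against 0.606 (U1U2) and 0.534 (promoter) with NT cells. Such genes may favour the activated line, so these scores cannot decide the size of the response. A larger response remains a hypothesis.

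Mitotic and replication genes were higher in promoter than in NT cells in vehicle, with a median of 0.67. GC content and transcript length, depth and a single library were argued against as the whole cause: the median was 0.67 with offsets for GC and length, 0.66 with thinned libraries and 0.61 to 0.71 with 1 of the 6 libraries left out. The difference between the lines that the design names stays open, and no measure of growth was used here.

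Ribosomal protein pseudogenes were lower in promoter than in NT cells in vehicle, with 29 of 86 called, and in U1U2 cells, with 7. Without NT vehicle replicate 1, where they were most abundant, 14 and 1 were called, so that library may account for part of the pattern and the rest stays open; with GC and length offsets 30 and 14 were called. Lower expression of the parent genes was argued against: the 82 ribosomal protein genes had a median of 0.0928 (quartiles -0.00421 to 0.307). Reads shared between the pseudogenes and their parents were not tested, and no biological explanation was tested.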

How the results depend on the processing

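The GC and length offsets and the thinning were chosen only after the data were seen. For all the changes below the cause was not tested, except that stricter thresholds call fewer genes by construction. Counts are given in the order MPA in NT, U1U2 and promoter cells; U1U2 against NT, promoter against NT and promoter against U1U2 in vehicle; the same 3 in MPA; and the differences of MPA responses U1U2 minus NT, promoter minus NT and promoter minus U1U2. With an absolute log2 fold change of at least 1 the edgeR counts were 301, 563, 725, 36, 202, 24, 71, 203, 16, 16, 95 and 0 (that last with 804 genes at an unadjusted p under 0.05, 57 called by DESeq2 and 3 by limma-voom with no such threshold), with 209 genes shared by all 3 lines and 20 basal changes shared. At an adjusted p under 0.01 the first 11 were 557, 1096, 1391, 25, 481, 39, 145, 359, 19, 9 and 89, with 395 and 19 shared.

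With GC and length offsets the counts were 1435 for MPA in NT cells, 393, 1845 and 280 for the lines in vehicle, 506, 1061 and 88 in MPA and 108, 450 and 28 for the differences of responses. PGR in promoter against U1U2 cells in vehicle passed at -0.35, its difference of responses in U1U2 minus NT passed at -0.49, and that in promoter minus NT, which was not called, turned from 0.11 to -0.0352. With DESeq2 they were 451 for U1U2 against NT and 258 for promoter against U1U2 in vehicle, 86 for promoter against U1U2 in MPA, 115, 468 and 57 for the differences and 328 basal changes shared, and PGR passed at -0.46. With no filter they were 808 for U1U2 against NT in vehicle and 281, 758 and 18 for the differences, and PGR passed at -0.46. With only the groups compared fitted they were 491 and 1049 for MPA in NT and U1U2 cells, 4, 435 and 11 in vehicle, 85 for U1U2 and 16 for promoter against U1U2 in MPA, 8 for U1U2 minus NT and 0 for promoter minus U1U2 by edgeR (804 at an unadjusted p under 0.05 with all groups, 57 by DESeq2, 3 by limma-voom). Thinned libraries gave 75 for promoter against U1U2 in vehicle and 6 for promoter minus U1U2, and the stricter filter gave 9 for the latter.

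The replicate numbers did not pair the libraries: of 45 pairs of libraries from different groups with the same number, 13 had a correlation over 0.1, from -0.52 to 0.50, and 4 of 18 libraries had their best partner under their own number. With the replicate number as a block the counts were 62 for U1U2 against NT and 69 for promoter against U1U2 in vehicle, 25 for promoter against U1U2 in MPA, 12, 150 and 0 for the differences (the last by edgeR, against 804 at an unadjusted p under 0.05 without the block, 57 by DESeq2 and 3 by limma-voom), and 51 basal changes shared.

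With an estimated correlation the camera adjusted p was 0.353, 0.368 and 0.269 for matrix genes under MPA in NT, U1U2 and promoter cells, 0.171 and 0.269 for interferon-stimulated genes in U1U2 and promoter cells, and 0.125, 0.0587 and 0.103 for mitotic genes under MPA in promoter cells, in promoter against NT in vehicle and in the difference of responses. These 8 are among 19 list tests that were followed through the alternatives, of which the other 11 kept their side of the threshold. Outside these 19, decidual, contractile, stress, p53, angiogenic, stromal and other lists also lost calls.

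With 1 library left out the counts ran from 612 (without NT vehicle replicate 2) to 972, 1267 to 1921 and 1565 to 2365 for MPA in the 3 lines, 23 to 639, 472 to 1347 and 39 to 64 in vehicle, 154 to 214, 390 to 490 and 15 to 40 in MPA and 8 to 47, 116 to 271 and 0 to 3 for the differences. PGR ran from -0.84 to -0.66, -1.28 to -1.11 and -0.68 to -0.55 under MPA, 1.99 to 2.17, 1.53 to 1.70 and -0.54 to -0.37 in vehicle, and 1.53 to 1.73, 1.67 to 1.85 and 0.03 to 0.21 in MPA. Over all alternatives, 205 of 210 PGR values, 132 of 234 counts of genes, 68 of 76 values of those 19 list tests, 183 of 210 counts of named genes and 24 of 42 overlaps stayed on their side of the threshold or within 1.5 times. PRL and IGFBP1 had 0 to 7 counts per library, and whether low expression or depth set this was not tested. In counts simulated from the NT vehicle means edgeR recovered 11% of genes whose responses differed 1.5-fold and 58% of those that differed 2-fold. Whether depth, the number of libraries or their spread set this recovery was not tested.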

Other observations

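The axes of variation within groups were examined only after the data were seen. In NT cells, MPA also changed single vascular and contractile genes. Of 26 angiogenic and vascular factors, 1 rose and 6 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.00668, lost at adjusted p = 0.249 with an estimated correlation), with STC1, stanniocalcin, at -1.26 ± 0.19 and FGF9 at -1.66 ± 0.14. Of 26 contractile and myofibroblast genes, 3 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0137, lost at adjusted p = 0.387 with an estimated correlation), and 6 rose without NT vehicle replicate 1. ACTG2, a smooth muscle actin, rose by 1.48 ± 0.19, ANKRD1 by 1.85 ± 0.17 and OGN, a proteoglycan, by 1.83 ± 0.22. DMD, dystrophin, rose by 1.94 ± 0.14. The WNT ligand WNT2 fell in NT cells (-0.92 ± 0.09) and in promoter cells (-1.59 ± 0.09).

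Under MPA in promoter cells, single members of lists that did not pass as a whole changed. HIF1A rose by 0.80 ± 0.10. The stromal transcription factors PRRX1 (-0.66 ± 0.10) and TWIST2 (-0.81 ± 0.12) fell, as did PGRMC1 (-0.64 ± 0.13), a membrane protein that binds progestins, and GATA2 (-0.62 ± 0.11), a transcription factor that acts with PGR in the endometrium.

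Within groups, the first axis of variation held 27.9% of the variance and followed GC content across 8747 genes (Pearson -0.84), and the second held 24.6%.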
